A study of Rattus norvegicus with 10 samples.

How the data were processed

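Left hippocampal RNA of 5 untreated and 5 ibudilast-treated male transgenic rats was measured in 1 library per rat. Groups and replicate numbers were taken from the sample titles. Per the labels, libraries were made with a stranded poly(A) mRNA kit from RNA isolated with a column kit. The deposited tables hold expected counts per gene symbol, estimated by the authors and not normalized, and a second table of a normalized signal, in which each count was divided by a library size scaled by its TMM factor. The submitters' processing notes name bcl2fastq, Bowtie2 2.1.0, RSEM 1.2.15, edgeR and the rn6 build, without saying which step each served. The annotation and any filter were not given in the sources used here.

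Of the count values, 12% were not whole, and expected counts were rounded to whole numbers before testing. The table has 17168 rows, of which 0 had no gene name. Symbols turned into dates by a spreadsheet affected 25 rows, 2 of them duplicated, which stayed in the tests and are not named. All 20 columns of the tables were matched to samples by title and 0 were not matched. No pair of libraries of the same group agreed within sampling noise: the lowest chi-square per gene was 11.5, and correlations of log2 CPM within groups were 0.942 to 0.993. Pairs across groups were not compared. Replicates are separate rats per the series' design text.

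The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust fitting, TMM factors, filterByExpr and Benjamini-Hochberg adjustment over the 12355 genes kept, at a threshold of 0.05. CPM values per rat used library sizes scaled by TMM factors, and log2 CPM also a prior count of 2. Gene lists were tested by camera with a preset correlation of 0.01 and with an estimated one, by fry, and by an exact permutation test of the list mean. Of 47 lists, 45 had at least 3 measured members, and the lists of mitochondrially encoded genes and nuclear long noncoding RNAs had fewer and were not tested. On simulated counts with these library sizes, means and dispersions, 16 of 100 genes changed by 0.5 on the log2 scale and 62 of 96 changed by 1 were recovered among 12291 genes, with 1 false call among 79. Only 200 genes were changed in that simulation, far fewer than passed in the rats, which makes the adjusted threshold stricter, so these shares are not recovery rates for the real comparison. A simulated shift of the proteasome list was recovered and 0 other lists were called. The settings of that simulation did not include correlation between genes, which was estimated at 0.921 for ribosomal proteins in the rats. The 0 therefore cannot tell how often camera calls lists by chance in the real data. Other splits of the rats into groups gave a median of 15 lists by camera with its preset correlation.

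The rule for named genes, set before the data were examined, took the 12 largest rises and 12 largest falls among genes that passed, with a group mean of at least 1 CPM in either group, all 5 ibudilast rats on one side of the untreated mean, and no placeholder symbol. It added up to 4 members of each list by smallest p, and the genes Pde3a, Pde4a, Pde4b, Pde4c, Pde4d, Pde10a, Pde11a, Mif, Tlr4, App, Apoe, Trem2 and Gfap. Results of some genes that the rule names are not reported here. Lists, tests and most alternatives were fixed then too. The replicate numbers are shared by both groups but did not pair the rats, so the main fit has no block. Alternatives were RLE, upper-quartile and no factors, DESeq2 1.42.0, edgeR's exact test, limma-voom, limma-trend on log2 of the authors' signal plus 1, no and stricter low-count filters (mean of 1 CPM and 10 counts in 5 libraries), a replicate block, 1 surrogate variable (sva 3.50.0), covariates of marker lists, other thresholds and leaving out each rat. Whole reads were recovered from the authors' normalized signal, with 100% of values whole within 0.01. Rat gene neighbours were taken from the GRCr8 annotation, matched by symbol for 97.9% of tested genes. It served only for which genes lie near each other, since the deposited tables were made on rn6, and no coordinates are given. For that check alone, abundance was the mean CPM over all 10 libraries without TMM factors. Gene length and GC content were not tested.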

Results

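RNA from the left hippocampus of 10 male TgF344-AD rats was sequenced. These Fischer 344 rats carry human transgenes, a mutant APP among them, and are used as a model of Alzheimer's disease. The 5 untreated rats ate plain rodent chow. The 5 ibudilast rats were given the drug, an inhibitor of cyclic nucleotide phosphodiesterases, from 5 months of age for 6 months, and all tissue was taken at 11 months. Libraries were stranded poly(A) libraries. Library totals were 17377762 ± 1122314 counts in the untreated group and 16146796 ± 1068409 counts in the ibudilast group (SD, n = 5 each), and single libraries held from 14806807 to 18533520 counts. Per the labels, the 5 ibudilast samples were kept in a tissue transition solution (RNAlater-ICE) and 0 of the untreated samples were, so that treatment and storage cannot be separated in any comparison here.

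The comparison asked which hippocampal transcripts differ between ibudilast-treated and untreated transgenic rats. With ibudilast, 76 of 79 cytosolic ribosomal protein genes, 48 of 73 nuclear-encoded respiratory chain genes and 13 of 23 oligodendrocyte markers rose. Of synapse genes 32 of 52 fell, of activity-dependent immediate early genes 20 of 37, of chaperones 14 of 29 and of cAMP signalling genes 10 of 23. The calls of these lists by camera were lost with an estimated correlation (adjusted p = 0.947, and for cAMP signalling adjusted p = 0.375, with an estimated correlation). Myelin basic protein (Mbp) went from 6512 ± 1869 to 11447 ± 924 CPM and the neuronal cytoskeletal gene Map2 from 1234 ± 312 to 322 ± 50.2 CPM (SD, n = 5). Camk2a, a kinase of excitatory synapses, went from 1765 ± 147 to 594 ± 218 CPM. Of 12355 genes tested, 5817 (47.1%) changed at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 3004 of them higher and 2813 lower with ibudilast. Most changes were moderate, with a median absolute log2 fold change of 0.573 among changed genes, while 575 genes were at least 2-fold higher and 375 at least 2-fold lower. The groups did not overlap for 4131 genes (33.4%), against 0.794% by chance. The first principal component of the libraries held 43.8% of the variance and parted the groups.

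The genes with the largest rises were mostly of low abundance. Tnfrsf4 and Tnfrsf25, both receptors of the tumour necrosis factor receptor family, rose by log2 fold changes of 2.98 ± 0.49 and 2.74 ± 0.39 (SE), to 1.26 ± 0.282 and 19.1 ± 7.40 CPM. Gsdma, a gasdermin, rose from 13.8 ± 3.20 to 86.0 ± 9.84 CPM (log2 fold change 2.64, adjusted p = 7.58e-06). Col7a1, a collagen of anchoring fibrils, rose from 2.74 ± 1.62 to 17.8 ± 2.64 CPM, and Cpt1b, a carnitine palmitoyltransferase of mitochondrial fatty acid import, from 1.25 ± 0.583 to 7.10 ± 3.21 CPM. Lad1, Rtbdn, Tssk3, Pdzd7, Gnb3 and N5 were also among the 12 largest rises, with log2 fold changes from 2.53 to 2.85. Tnfrsf4, Tssk3, Tnfrsf25, Col7a1, Gnb3 and N5 lie within 5 kb of a gene at least 10 times as abundant. Tssk3 lost its call with the oligodendrocyte list as a covariate (2.46, adjusted p = 0.0597). Rtbdn was at 6.74 CPM in untreated replicate 3 and at most 1.05 CPM in the other untreated rats.

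The largest falls included neuronal, glial and vascular genes. Map2 fell by 1.94 ± 0.18 on the log2 scale (adjusted p = 3.24e-05). Slc1a2, the main astrocyte glutamate transporter, fell from 474 ± 117 to 146 ± 40.9 CPM, and Flt1, a VEGF receptor of endothelial cells, from 83.6 ± 25.9 to 22.3 ± 3.92 CPM. Pcdh8, an activity-regulated protocadherin, fell from 125 ± 24.7 to 37.1 ± 9.61 CPM, and Dok6, an adaptor of receptor tyrosine kinases, from 35.2 ± 13.2 to 8.70 ± 2.66 CPM. Npy2r, a neuropeptide Y receptor, had a log2 fold change of −2.13, the growth factor gene Hgf of −1.90, the apoptosis gene Pmaip1 of −1.91, the GABA-A receptor subunit gene Gabre of −1.85 and the immediate early gene Egr2 of −1.72. Cyp2a3, at −2.26, and Egr2 passed with all rats but not without untreated replicates 2 and 3 and ibudilast replicates 1 and 4 (−1.02 and −1.29, adjusted p = 0.0762 and 0.114), libraries that stood apart by their marker genes. With the oligodendrocyte list as a covariate Cyp2a3 was at −1.05 (adjusted p = 0.332) and Egr2 at −1.31 (0.163). Egr2 also lost its call by limma-voom (−1.41, 0.0582), and Gabre with the excitatory neuron list as a covariate (−1.58, 0.0639). Hspa1a, an inducible HSP70 gene, was at 25.1 ± 10.5 CPM in untreated and 0.293 ± 0.309 CPM in ibudilast rats, the largest fall of all (log2 fold change −6.35), but its near-identical copy Hspa1b rose from 15.4 ± 1.96 to 28.7 ± 2.08 CPM. Reads can be split between the copies, so each value is uncertain. Their sum was 40.5 ± 11.6 CPM in untreated and 29.0 ± 2.0 CPM in ibudilast rats (exact permutation test, two-sided, p = 0.0476).

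**Figure D1:**
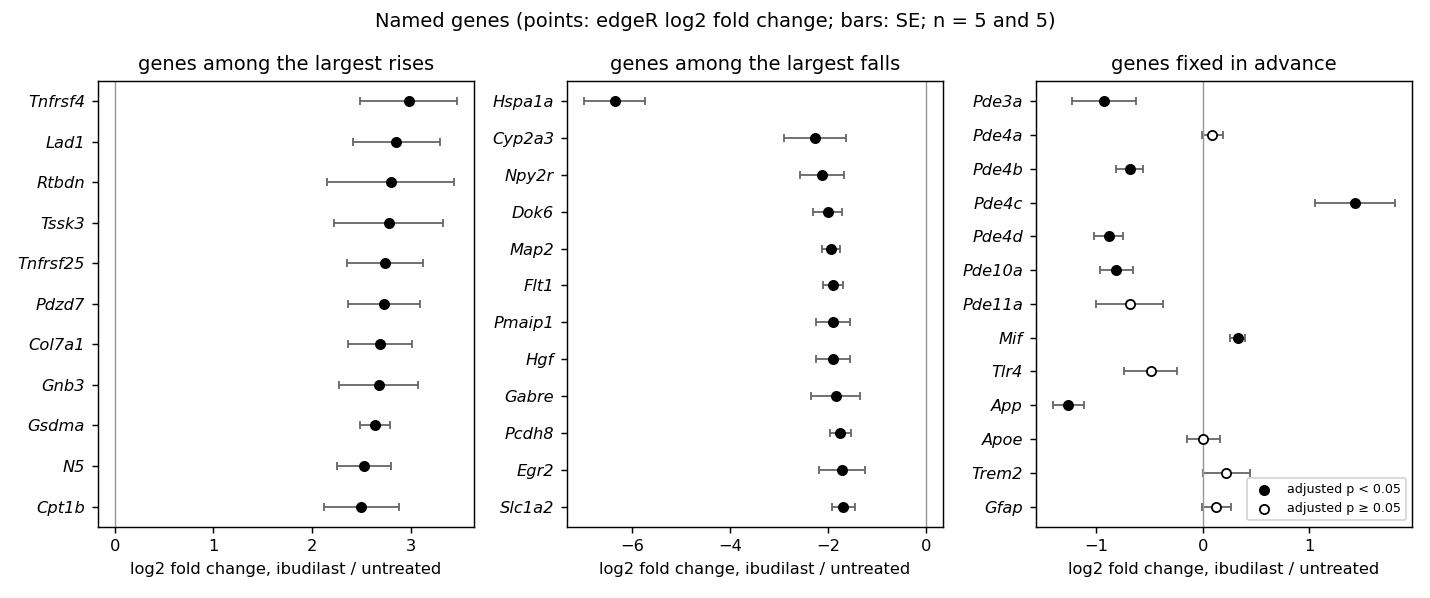
Log2 fold change (horizontal axis, ibudilast over untreated) of 11 of the 12 genes with the largest rises, the 12 with the largest falls and 13 genes fixed in advance, as points with standard errors from edgeR, n = 5 and 5. Filled points passed an adjusted p of 0.05; Hspa1a lies far from the other falls, at −6.35, and Pde4a, Pde11a, Tlr4, Apoe, Trem2 and Gfap are open points.

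Members of the phosphodiesterase family, part of which ibudilast inhibits, went both ways. Of 19 measured members, 3 rose, 9 fell and 7 did not pass, and the counts were the same adjusted over the list alone. Pde4d fell by 0.88 ± 0.14, Pde4b by 0.69 ± 0.13, Pde10a by 0.81 ± 0.16 and Pde8b by 0.68 ± 0.14 on the log2 scale. Pde3a was at −0.93 (adjusted p = 0.0265), a call that was lost without untreated replicate 1 (0.0630) or without ibudilast replicate 2 (0.0625), 3 (0.0541) or 5 (0.0636), with library size alone (0.0546), at −0.79 to −0.84 in these, and with the oligodendrocyte list as a covariate (−0.68, 0.320). Pde4c rose by 1.43 ± 0.38 from 1.28 ± 0.866 CPM. Pde4a was at 0.09 (adjusted p = 0.460) and Pde11a at −0.69 (0.0979). The list mean was 4.29 ± 0.0790 log2 CPM in untreated and 4.01 ± 0.0876 in ibudilast rats (exact permutation test, adjusted p = 0.0275), while camera, which compares a list with all other genes, gave an adjusted p of 0.133.

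Genes of cAMP and protein kinase A signalling fell as a list (camera adjusted p = 0.0143, adjusted p = 0.375 with an estimated correlation), with 2 members higher, 10 lower and 11 not passing, the same adjusted over the list alone. Pkia, an inhibitor of protein kinase A, fell from 72.1 ± 6.67 to 30.3 ± 2.79 CPM. The kinase subunits Prkar1a and Prkacb fell by 0.85 and 1.11 on the log2 scale, and the adenylyl cyclase Adcy1 by 1.40. Among other proteins reported as ibudilast targets, Mif rose by 0.33 ± 0.07 (adjusted p = 0.00329), and Tlr4 was at −0.49 (adjusted p = 0.132). In the list of TLR4, NF-kB and cytokine genes, 4 of 24 rose, 4 fell and 16 did not pass (camera adjusted p = 0.863), the same adjusted over the list alone. Il18 rose by 1.15 and Il1rn, the IL-1 receptor antagonist, by 1.19, while the adhesion molecule Vcam1 fell by 0.85.

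Synapse and neurotransmission genes fell, with 32 of 52 members lower, 0 higher and 20 not passing (34 lower adjusted over the list alone; camera adjusted p = 1.12e-08, adjusted p = 0.947 with an estimated correlation). Nrxn3, a presynaptic adhesion molecule, fell from 101 ± 12.7 to 57.4 ± 5.06 CPM, and Pclo and Nlgn3 fell by 1.12 and 0.76 on the log2 scale. Activity-dependent immediate early genes fell too, 20 of 37 lower, 0 higher and 17 not passing, the same adjusted over the list alone (camera adjusted p = 1.19e-04, adjusted p = 0.947 with an estimated correlation). Rheb, Jun and Pcsk1 fell by 0.52, 0.96 and 1.12. Among excitatory neuron markers, 3 of 13 fell, Camk2a, Nptx1 and Grin2a, and 10 did not pass (1 lower adjusted over the list alone, camera adjusted p = 0.101). Nptx1 was at −1.20, a call that was lost without untreated replicate 1 (adjusted p = 0.0688), 2 (0.0502) or 5 (0.0557) or ibudilast replicate 1 (0.0574), at −1.07 to −1.18, and with the oligodendrocyte list as a covariate, where it was at −1.41 (0.102). That list mean was 7.30 in untreated replicate 3 and 5.67 in ibudilast replicate 4, each below the rest of its group. In the dentate granule list 6 of 11 fell and 5 did not pass (the same adjusted over the list alone, camera adjusted p = 0.0814), in the CA3 list 4 of 7 fell and 3 did not pass (also the same, 0.289), and in the CA1 list 1 of 9 fell, Man1a1, and 8 did not pass (also the same, 0.513). Stxbp6 fell by 1.51, Calb1 by 0.50, Pvrl3 by 0.97 and Cpne4 by 1.53. With the oligodendrocyte list as a covariate Calb1 was at −0.16 (adjusted p = 0.356). Of 19 interneuron markers, 6 fell, 1 rose and 12 did not pass (the same adjusted over the list alone, camera adjusted p = 0.220), with Cnr1 at −1.54 and Gad2 at −0.90.

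Ribosomal and respiratory chain genes moved the other way. Of 79 cytosolic ribosomal protein genes, 76 rose, 0 fell and 3 did not pass (78 higher adjusted over the list alone; camera adjusted p = 2.70e-14, adjusted p = 0.947 with an estimated correlation). Rpl41 rose by 0.84 and Rpl28 by 0.60 on the log2 scale. The list mean of untreated replicate 3, 8.37 log2 CPM, lay beside the ibudilast mean of 8.46 ± 0.0769, while the untreated mean was 7.93 ± 0.260. Of 73 nuclear-encoded genes of oxidative phosphorylation, 48 rose, 5 fell and 20 did not pass (51 higher and 5 lower adjusted over the list alone; camera adjusted p = 2.77e-07, adjusted p = 0.947 with an estimated correlation). Ndufa2 rose by 0.69, Cox7b by 0.66 and Atp5e by 0.70, while Ndufs1, a core subunit of complex I, fell by 0.67. The share of counts from the ribosomal RNA genes Rn45s and Rn28s was 6.83 ± 3.01% in untreated and 9.26 ± 2.42% in ibudilast rats.

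Among genes of protein folding and turnover, more chaperone and ubiquitin enzyme genes fell than rose, while the proteasome had more members higher than lower. Of 29 heat shock and chaperone genes, 14 fell, 2 rose and 13 did not pass (15 lower and 2 higher adjusted over the list alone; camera adjusted p = 0.00257, adjusted p = 0.947 with an estimated correlation). The mean log2 fold change of the list was −0.48, and −0.28 without Hspa1a, whose value is uncertain (camera adjusted p = 0.00477, adjusted p = 0.947 with an estimated correlation). The groups then overlapped, at 6.59 log2 CPM in untreated replicate 3 and 6.65 in ibudilast replicate 1, and the list did not pass the exact permutation test (adjusted p = 0.0765). Without both copies the mean was −0.32, with the same exact result. Dnajb4 fell by 1.01 and Hsp90b1, a chaperone of the endoplasmic reticulum, by 0.56. Of 52 ubiquitin enzyme genes, 26 fell, 6 rose and 20 did not pass (27 lower and 8 higher adjusted over the list alone; camera adjusted p = 0.00477, adjusted p = 0.947 with an estimated correlation). Ube2j1, Itch and Uba1 fell by 0.73, 0.83 and 0.60. Of 41 proteasome genes, 9 rose, 2 fell and 30 did not pass, the same adjusted over the list alone (camera adjusted p = 0.428), with Psmb6 at 0.35. Of 48 autophagy and lysosome genes, 8 rose, 12 fell and 28 did not pass (7 higher and 12 lower adjusted over the list alone, camera adjusted p = 0.373). Optn fell by 0.51 and Atg16l1 rose by 0.54. That list's mean was 6.65 ± 0.0173 log2 CPM in untreated and 6.58 ± 0.0208 in ibudilast rats (exact permutation test, adjusted p = 0.0275). The difference, −0.0775, was small and ran from −0.106 to −0.00786 over the alternatives. Exact tests were run on TMM-scaled values alone, so this result may depend on the scaling. Of 24 cholesterol synthesis genes, 13 fell, 3 rose and 8 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0237, adjusted p = 0.947 with an estimated correlation). Sc5d, Stard4 and Hmgcs1 fell by 0.75, 0.83 and 0.82. The list's call was lost without ibudilast replicate 1 (camera adjusted p = 0.0563), without the 4 libraries that stood apart (0.0633) and with the excitatory neuron list as a covariate, where the mean log2 fold change went from −0.27 to −0.14 (0.109), and it did not pass by fry (0.0633).

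Among amyloid and Alzheimer risk genes, 16 of 36 fell, 6 rose and 14 did not pass (17 lower and 6 higher adjusted over the list alone; camera adjusted p = 0.0353, adjusted p = 0.375 with an estimated correlation). Without untreated replicate 3 the camera adjusted p of this list was 0.0721, and without the 4 libraries that stood apart it was 0.0633. With the oligodendrocyte list as a covariate it was 0.0667, at a mean log2 fold change of −0.26 against −0.27. Aplp2 fell from 610 ± 22.1 to 355 ± 23.5 CPM, Cdk5r1 by 0.98 and the alpha-secretase Adam10 by 0.70 on the log2 scale. App went from 2448 ± 474 to 1019 ± 88.5 CPM (log2 fold change −1.26, adjusted p = 9.61e-05). The table holds a single App row, in which reads of the human transgene were not told apart from those of the rat gene. Apoe was at 5974 ± 1364 and 5992 ± 611 CPM (adjusted p = 0.985), with 8376 CPM in untreated replicate 3.

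Glial and vascular markers did not move together. Of 23 oligodendrocyte markers, 13 rose, 0 fell and 10 did not pass (14 higher adjusted over the list alone; camera adjusted p = 0.00257, adjusted p = 0.947 with an estimated correlation). Hapln2 rose from 49.6 ± 10.4 to 220 ± 47.4 CPM, and Sgk2, Aspa and Mbp rose by 1.05, 0.76 and 0.81 on the log2 scale. Without untreated replicates 2 and 3 and ibudilast replicates 1 and 4, the mean log2 fold change of the list went from 0.59 to 0.35 and its call was lost (camera adjusted p = 0.0634). Homeostatic microglia markers fell, with 10 of 18 lower, 0 higher and 8 not passing, the same adjusted over the list alone (camera adjusted p = 0.0136, adjusted p = 0.947 with an estimated correlation). Itgam fell by 1.43, P2ry12 by 1.36 and Gpr34 by 1.13. Without untreated replicate 3, which had the highest mean of that list (5.39 log2 CPM), its camera adjusted p was 0.0832, and without the 4 libraries that stood apart it was 0.0633. Endothelial markers fell, 8 of 18 lower, 0 higher and 10 not passing, the same adjusted over the list alone (camera adjusted p = 0.00279, adjusted p = 0.947 with an estimated correlation). Slco1c1, Tek and Emcn fell by 0.94, 1.26 and 1.02. Of 21 complement genes, 6 fell, 0 rose and 15 did not pass, the same adjusted over the list alone (camera adjusted p = 0.0373, adjusted p = 0.947 with an estimated correlation). C3 fell by 1.18. The complement call was lost without untreated replicate 2 (camera adjusted p = 0.0612) or 3 (0.142) and without ibudilast replicate 2 (0.0726) or 3 (0.0832). By fry, the homeostatic microglia and complement lists did not pass (adjusted p = 0.149 and 0.150). With the oligodendrocyte list as a covariate, the mean log2 fold change went from −0.74 to −0.52 for endothelial (camera adjusted p = 0.0868), from −0.49 to −0.18 for homeostatic microglia (0.432) and from −0.45 to −0.34 for complement genes (0.325), and these calls were lost. Slco1c1 (−0.52, 0.118), Tek (−0.96, 0.0909), Emcn (−0.68, 0.114) and Gpr34 (−0.72, 0.0520) lost theirs there too. The oligodendrocyte list mean did not overlap between the groups, so losses under this covariate do not show what caused a change. Of 17 astrocyte markers, 7 fell, 0 rose and 10 did not pass, the same adjusted over the list alone (camera adjusted p = 0.106). Gja1 fell by 0.68, a call that was lost with the oligodendrocyte list as a covariate (−0.50, 0.0554). Gfap was at 0.13 (adjusted p = 0.469) and Trem2 at 0.22 (adjusted p = 0.438).

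**Figure D2:**
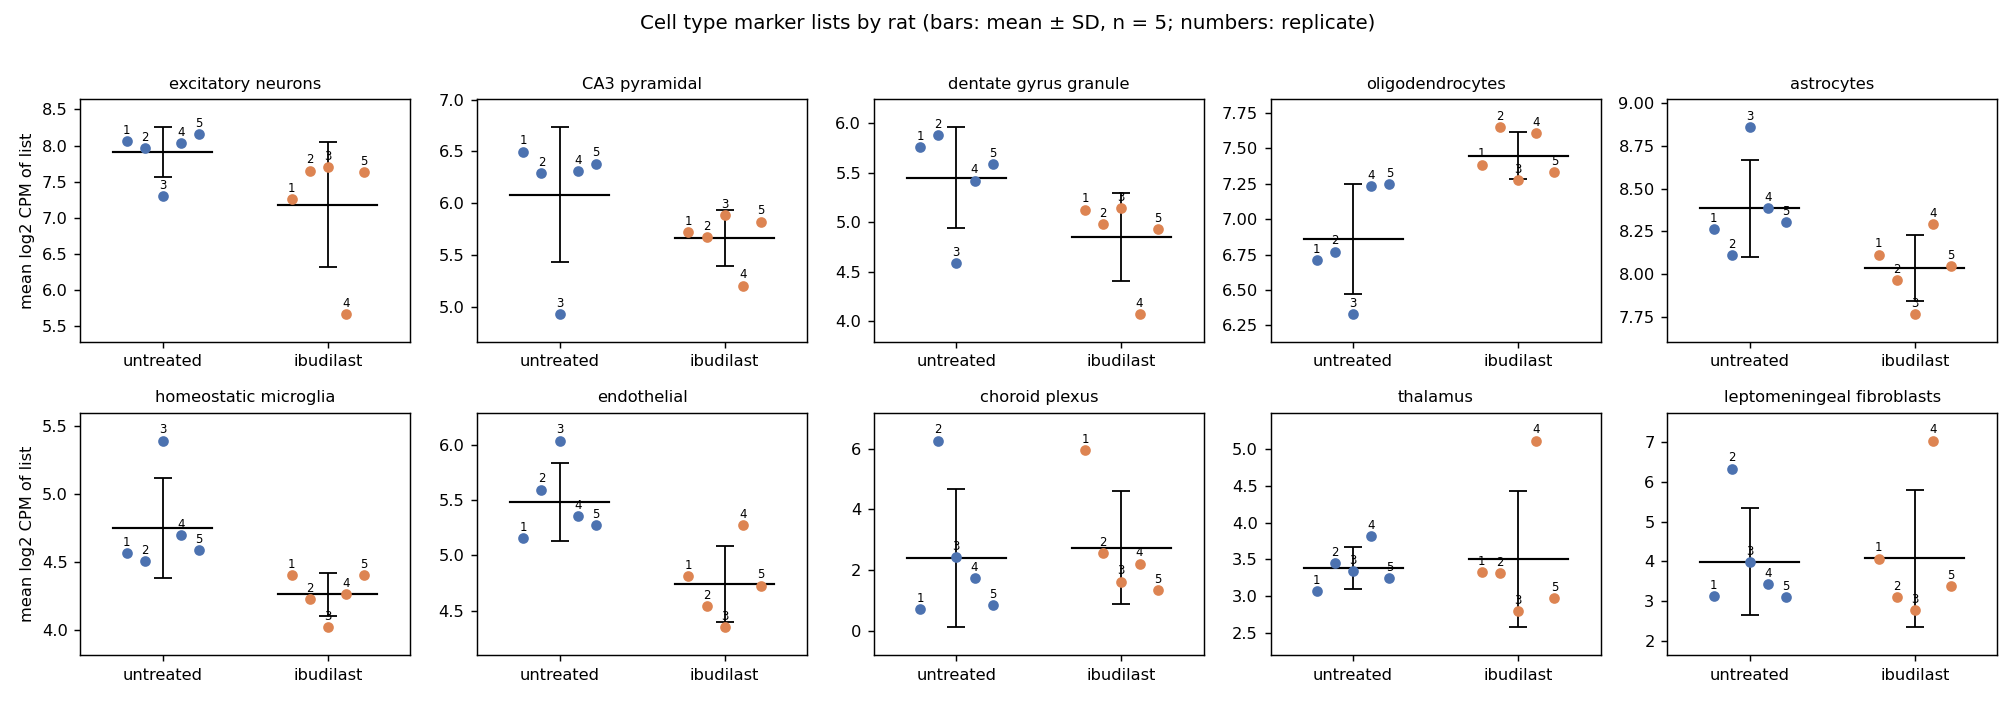
Mean log2 CPM of 10 cell type marker lists (vertical axes) in each rat, with the replicate number beside each point and the group mean ± SD, n = 5. Untreated replicate 2 and ibudilast replicate 1 stand apart in the choroid plexus panel at 6.26 and 5.95, and ibudilast replicate 4 in the thalamus panel at 5.12. In the leptomeningeal panel untreated replicate 2 lies at 6.33 and ibudilast replicate 4 at 7.04.

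Exact permutation tests of the list means over the 252 assignments of the rats, two-sided, gave 13 of 45 lists at an adjusted p of 0.0275, the value reached when the groups did not overlap at all (smallest p possible 0.00794). These were the lists named above as changed by camera except endothelial (0.0510) and complement (0.179), together with phosphodiesterases and autophagy and lysosome. Heat shock genes were among them only with Hspa1a in the list. Autophagy and lysosome genes were among them with a mean difference of only −0.0775 on the log2 scale. Some other separations were narrow too. For ribosomal proteins, untreated replicate 3 and ibudilast replicate 4 were both at 8.37 log2 CPM to the digits given. The lowest untreated and highest ibudilast means were 6.587 and 6.568 for ubiquitin enzymes and 5.765 and 5.747 for cholesterol synthesis. For phosphodiesterases they were 4.171 and 4.144. Fry, which tests whether a list moves on balance one way, gave 14 lists at an adjusted p under 0.05: those changed by camera except homeostatic microglia, complement and cholesterol synthesis, together with phosphodiesterases, autophagy and lysosome, adult neurogenesis and hypoxia response. Camera with its preset correlation called at least as many lists in 78 of 100 splits of the rats, the real one included, so the number of lists it called is not larger than other groupings of these rats give.

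**Figure D3:**
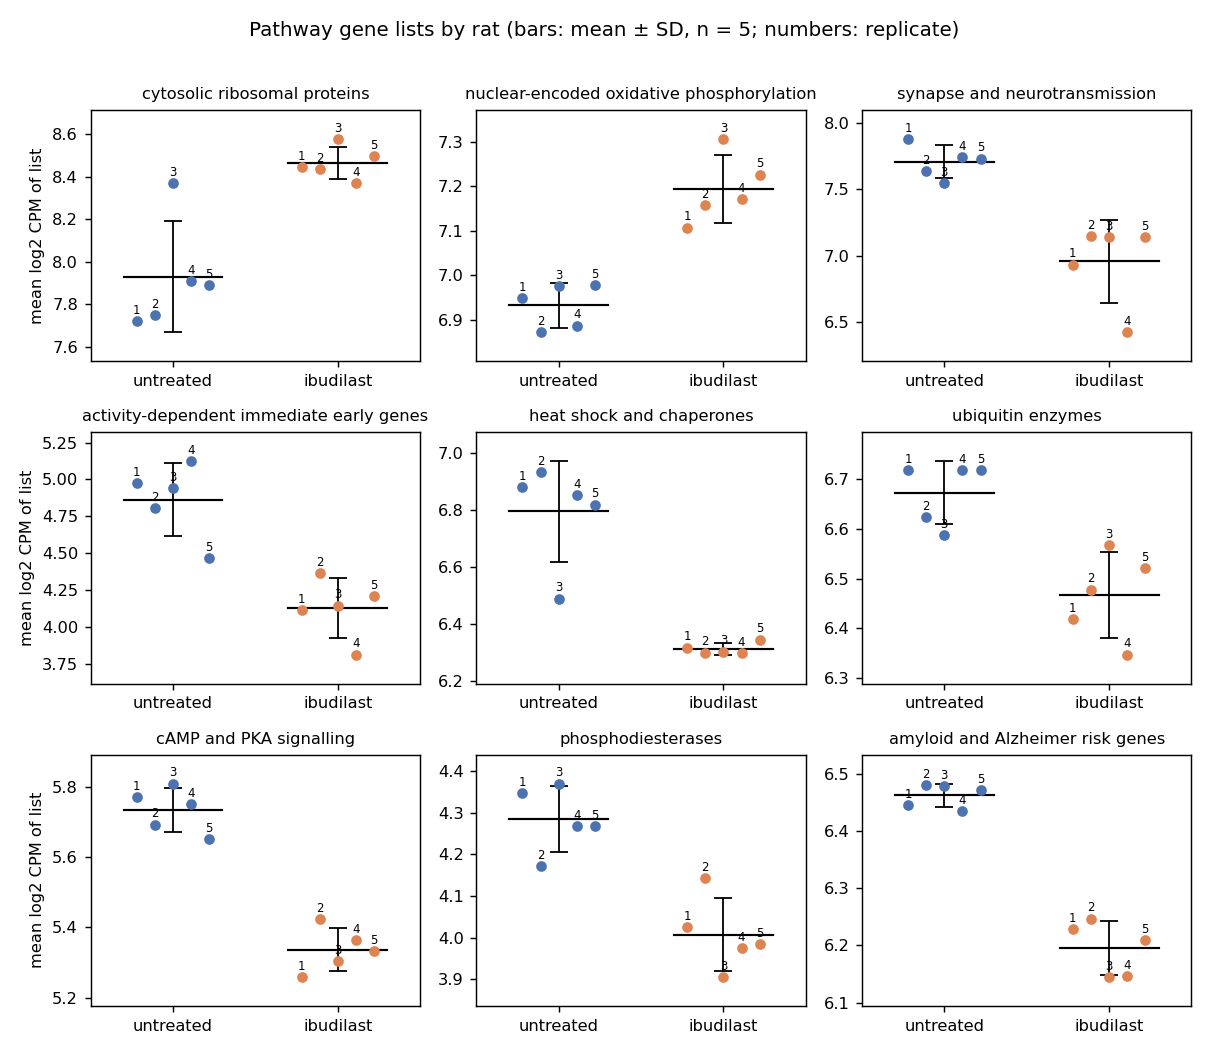
Mean log2 CPM of 9 pathway gene lists (vertical axes) in each rat, with the replicate number beside each point and the group mean ± SD, n = 5. The groups do not overlap in any of the 9 panels, though narrowly in some, and heat shock genes are drawn with Hspa1a included. In the ribosomal protein panel untreated replicate 3 lies at 8.37, beside ibudilast replicate 4.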

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

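Values in 1 rat far from the rest of its group were looked for in 168 groups of 5 values (45 gene lists, 3 library measures and 36 named genes), and 20 exceeded Dixon's 95% critical value of 0.71. Chance flags about 1 group in 20, here 8.4. Untreated replicate 3 accounted for 9 and ibudilast replicate 4 for 7. The tests of cell composition and of neighbouring genes below were chosen after the result was seen. The 4 libraries left out below were likewise picked by their marker values in these data. Untreated replicate 3, compared with other untreated rats below, also stood out in these same values.

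Untreated replicate 3 was low for excitatory neuron (7.30 log2 CPM, others 7.97 to 8.16) and CA3 markers (4.93, others 6.29 to 6.5) and for heat shock genes (6.49, others 6.82 to 6.93), and high for homeostatic microglia (5.39, others 4.51 to 4.70). Its Rtbdn was 6.74 CPM against at most 1.05 in the others, Cyp2a3 4.18 against at most 1.26, Pde4c 2.81 against at most 1.08, Flt1 128.6 against at most 79.96 and Apoe 8376 against at most 5730. Ibudilast replicate 4 was low for excitatory neuron (5.67, others 7.26 to 7.71) and dentate granule markers (4.07, others 4.93 to 5.14) and high for mural cell (4.57, others 2.97 to 3.33) and thalamus markers (5.12, others 2.80 to 3.33). Its Pdzd7 was 35.1 CPM against 11.9 to 15.8, Gnb3 8.56 against 4.29 to 5.21 and Pcdh8 20.0 against 40.7 to 42.0. Choroid plexus markers were at 5.95 in ibudilast replicate 1 (others 1.36 to 2.57), leptomeningeal markers at 6.33 in untreated replicate 2 (others 3.09 to 3.98), CA1 markers at 6.19 in untreated replicate 5 (others 5.63 to 5.73) and Pde4b at 29.4 CPM in untreated replicate 2 (others 39.8 to 41.6). Ibudilast replicate 4 had a still higher leptomeningeal mean, 7.04 (others of its group 2.76 to 4.07), without exceeding the critical value. The same held for choroid plexus markers in untreated replicate 2, at 6.26 (others 0.717 to 2.44).

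The size of the group difference, 5817 of 12355 genes, was weighed first. A chance arrangement of the rats is unlikely to account for it, since only 1 of 100 splits, the real one, called as many genes. The highest other split called 0. A share of 1 in 100 is the smallest these splits can give, and they cannot tell what else differed between the groups. Other tissue in the 4 libraries that stood apart does not alone account for it, since 6857 genes changed without them. The genes called with all rats kept their direction there in 100% of 5809, and the slope of new on old fold changes was 1.02. These calls had used the kept rats too, so the same direction and the slope were largely built in. Other tissue that differed between the groups among the kept rats was not tested and stays open. Storage and treatment, the difference the design names, both stay open and cannot be told apart, since 0 libraries were stored the other way round than the rest of their group. For the number of lists called by camera, 13, chance is not excluded, as 78 of 100 splits called as many, up to 26, a result that bears on that number and not on the exact tests of single list means.

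Synapse genes fell and ribosomal protein genes rose, while the excitatory neuron list was lower without passing (camera adjusted p = 0.101). A lower share of neurons alone would raise the markers of other cell types alike. Oligodendrocyte and endothelial markers moved apart by 1.33 on the log2 scale (exact permutation test, two-sided, p = 0.00794). Both lists were picked after the rise of one and the fall of the other were seen, so this p restates those results. It cannot decide whether a lower share of neurons contributed. A difference that also occurs between untreated rats may contribute: untreated replicate 3 minus replicates 1 and 2 correlated across genes with ibudilast minus untreated replicates 4 and 5 by r = 0.312 (genes are not independent replicates). Replicate 3 was 0.552 higher for ribosomal proteins and 0.198 lower for synapse genes than the other untreated rats, and over all ways to part the untreated rats r was 0.238 to 0.433 for replicate 3 and −0.413 to 0.251 for the others. Its synapse mean of 7.55 log2 CPM stayed above the ibudilast mean of 6.96. Replicate 3 also went against the ibudilast change in places. Among untreated rats it was highest for Map2 (1733 CPM), Slc1a2 (653 CPM), endothelial (6.04) and homeostatic microglia markers (5.39), and lowest for oligodendrocyte markers (6.33). Excitatory neuron markers were lower in it, as with ibudilast. Such a difference could account for part of the pattern at most. Gene length and GC content were not tested, so a contribution from either to the synapse and ribosomal pattern stays open.

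Between 1 and 30 CPM, 276 of 763 genes within 5 kb of a gene at least 10 times as abundant rose (36.2%), 33 fell and the others did not pass, while of 3847 genes with no more abundant neighbour 16.8% rose and 21.4% fell. The median log2 fold changes were 0.41 and −0.05. At matched abundance the difference was 0.441 (permutation p = 0.0001, the smallest that 10000 permutations can give). At any abundance, 347 of the 2917 matched genes that rose (11.9%) had such a neighbour, as did 6 of the 12 largest rises and 0 of the 12 largest falls. These shares were not matched on abundance, and several of the largest falls, such as Map2 and Slc1a2, were abundant genes. The share among all matched genes was not computed. Strand was not considered when neighbours were counted. The permutations shuffled genes and not rats, so their p does not measure the spread between rats. Reads from neighbouring transcripts may account for part of the largest rises, but genes were matched on abundance alone. Gene length and GC content were not tested, so a contribution from either stays open here too. A biological explanation for these rises was not tested.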

How the results depend on the processing

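Of the alternatives run, leaving out the 4 libraries, leaving out the rRNA rows, the excitatory neuron covariate, the recovered reads and the heat shock list without Hspa1a or both copies were chosen after seeing the data. The count of 5817 genes stayed within 1.5 times under all but 2. A fold change of at least 1.5 left 2826 genes (1391 higher, 1435 lower), as its construction requires. The oligodendrocyte covariate left 3815 (2001 higher, 1814 lower) and 8 lists. The mean of that list did not overlap between the groups, at most 7.25 log2 CPM in untreated and at least 7.27 in ibudilast rats. The covariate therefore follows the group closely, which widens the errors of the group effect. A call lost under it does not show that oligodendrocyte content caused the change, and this was not tested. The oligodendrocyte covariate ended 19 calls of named genes outside its own list, and the calls of the endothelial, homeostatic microglia, complement and amyloid lists. The 13 lists became 0 with an estimated correlation. That correlation was 0.921 for ribosomal proteins, but 0.00281 for cAMP signalling and −0.00439 for amyloid genes, below the preset 0.01. For cAMP signalling and amyloid genes a higher correlation was thus not what ended the call, and the cause was otherwise not tested. Leaving out each rat gave 5115 to 6292 genes (2549 to 3068 higher, 2461 to 3224 lower) and 11 to 14 lists. Without the 4 libraries 6857 genes and 10 lists changed, and recovered reads gave 5817 genes. Without scaling factors 59.8% of changed genes were higher, against 51.6%. Of the 5817 genes, 4 turned sign under the oligodendrocyte covariate, 2 of them members of its list, and none under the other alternatives; 0 of the 4 passed there. The replicate block gave 4726 genes and 14 lists, and Gabre, Nptx1 and Cpne4 did not pass under it (−1.63, −1.23 and −1.53, adjusted p = 0.0555, 0.0850 and 0.0546); same-numbered rats correlated by −0.328 to 0.416, over 0.1 in 1 of 5 pairs, and 1 rat matched its own number best. A list used as covariate has its own result fixed, so it was left out there and its members are not counted among the calls it ended.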

Other observations

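Several lists not described above held changed members without a call by camera, and the adult neurogenesis list had 6 of 18 lower, 0 higher and 12 not passing (5 lower adjusted over the list alone, camera adjusted p = 0.101), among them Ncam1 and Dpysl3. Circadian clock genes went both ways, 3 up, 4 down and 9 not passing of 16, the same adjusted over the list alone (0.835). Per3 rose from 20.0 ± 3.36 to 45.5 ± 11.9 CPM and Per2 by 0.71, while Clock fell by 0.35 on the log2 scale. Of 21 glucocorticoid response genes, 7 rose, 1 fell and 13 did not pass, the same adjusted over the list alone (0.383), and Tsc22d4 rose by 0.53. Of 29 antioxidant genes regulated by NRF2, 9 rose, 8 fell and 12 did not pass, the same adjusted over the list alone (0.893), with Gpx4 at 0.81 and Sod2 at −0.47. The hypoxia list had 3 up, 8 down and 13 not passing of 24 (3 and 7 adjusted over the list alone, 0.263), and Vegfa rose by 0.68 while P4ha1 fell by 0.62. Among transporters and enzymes of xenobiotics, 3 rose, 5 fell and 17 did not pass of 25, the same adjusted over the list alone (0.835), and Abca7 rose by 1.06. Of 22 neurotrophic factor and receptor genes 3 rose, 4 fell and 15 did not pass, the same adjusted over the list alone (0.579), with Lifr at −1.09.

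Of 11 oligodendrocyte precursor markers, 2 rose, 3 fell and 6 did not pass, the same adjusted over the list alone (camera adjusted p = 0.707), with Tnr at −0.96 and Bcas1, an early myelinating marker, at 0.67. The disease-associated microglia list had 1 higher, 6 lower and 18 not passing of 25, the same adjusted over the list alone (0.434), with Hif1a at −0.92. Of 24 reactive astrocyte genes, 2 rose, 5 fell and 17 did not pass (1 and 2 adjusted over the list alone, 0.428), with Aspg at 1.55. Interferon response genes had 1 higher, 6 lower and 30 not passing of 37 (1 and 4 adjusted over the list alone, 0.263), with Oas1b at 1.09. Antigen presentation had 1 higher, 0 lower and 18 not passing of 19, the same adjusted over the list alone (0.835), and histones 2 higher, 1 lower and 14 not passing of 17 (2 and 0 adjusted over the list alone, 0.428). Striatal markers had 1 higher, 2 lower and 11 not passing of 14 (1 and 1 adjusted over the list alone, 0.835), neocortical ones 1, 4 and 6 of 11 (also 1 and 4, 0.290) and mural cell ones 0, 3 and 11 of 14 (also 0 and 3, 0.579). Of 13 thalamic markers 1 fell, Rorb, and 12 did not pass (also 1 adjusted over the list alone, 0.950), and of 5 blood leukocyte markers 1 rose, Ly6g6e, and 4 did not pass (also 1, 0.950). None passed among 9 ependymal (0.513), 20 choroid plexus (0.911), 18 leptomeningeal (0.950) or 4 erythrocyte markers (0.992), nor adjusted over the list alone. The median, mean and camera direction did not share a sign for mural cells, circadian clock, NRF2, choroid plexus, blood leukocytes, thalamus and leptomeningeal fibroblasts.

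Ttr, the transthyretin gene of the choroid plexus, was at 7121 CPM in untreated replicate 2 and 6666 CPM in ibudilast replicate 1, and at most 317 CPM in the other rats. Ibudilast replicate 4 had 137 CPM of the thalamic marker Tcf7l2, against at most 14.6 in the others, and 236 CPM of Slc17a7, the vesicular glutamate transporter, against at least 1076. Its pituitary and hypothalamic hormone genes Pomc and Gh1 were at 33.9 and 8.74 CPM. These genes, other than Tcf7l2, were chosen after their values were seen.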
